A study of Danio rerio with 4 samples.

How the data were processed

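Total RNA extracted with Trizol from pools of 200 zebrafish embryos, kept at 28 °C with 14 h of light and 10 h of dark, was labelled by the authors from 1 µg with the Quick Amp kit and hybridized to 2-colour Agilent oligonucleotide arrays. Embryos had received 2 to 3 nl of morpholino at the 1-cell stage. Per the labels the morphant was in Cy5 and the wild type in Cy3 on each of 4 arrays, 2 at 12 hpf and 2 at 24 hpf. The pools are taken as the replicates, so p-values measure the spread between these arrays only. No dye swap is named, so a difference between dyes and a difference between groups cannot be told apart within an age.

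Per the file headers the scans were read with Agilent Feature Extraction 10.5.1.1, and the spot and local background values are in units of fluorescence intensity, not normalized. The same deposited scanner tables hold processed signals, which are intensity values after background subtraction and dye normalization by that software, and a p-value of each log ratio from its error model, per the file headers. The value table deposited by the authors holds the log10 ratio of Cy5 over Cy3, and it equalled the scanner software's log ratio at every spot (largest difference 0). Between 18.6% and 20.8% of its noncontrol values per array were set to 0 by the software. The array was annotated by its maker on an earlier zebrafish assembly, and genomic positions are not used here.

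Median spot signals and median local backgrounds were used, since the tables hold no mean spot signal, although means had been chosen before the data were examined. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized by loess within each array, with control spots and the 10 to 18 spots per array that the software marked as outliers at weight 0. Of 45220 spots per array 1417 control spots were left out. The other 43803 spots were averaged to 43603 probes, 50 of which had 5 spots. No spot was saturated (0). A probe was kept if it was well above background in at least 1 channel on both arrays of at least 1 age, which left 28321. Symbols came from RefSeq accessions matched without their version to a reference table, for 16770 of 19210 probes with such an accession, and 26833 probes stayed without a symbol, 5314 of them with an Ensembl transcript identifier only.

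Ratios were fitted in limma 3.58.1 under R 4.3.3 with a mean per age over all 4 arrays (2 residual degrees of freedom, 7.50 prior degrees of freedom), each age against 0 and the 24 hpf mean minus the 12 hpf mean, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. All limma tests were two-sided. Wild-type levels at 24 against 12 hpf were tested in limma on Cy3 log2 intensities after loess within and Aquantile normalization between arrays, 2 arrays against 2. A gene was represented by its brightest probe. Named genes were the 10 largest rises and 10 largest falls per comparison among probes past the threshold that moved the same way on both arrays, with a symbol that is not a clone or locus name, plus up to 4 members of each list with the largest ratios and the targeted gene. For comparisons between ages, moving the same way meant the same sign in all 4 differences between single arrays. Genes shown for a list were taken from the named genes. The result of 1 member of a list is not reported here.

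The comparisons, tests, named-gene rule and 25 gene lists were fixed before the data were examined. The lists cover the Bcl-2 family, p53 targets, caspases and apoptosis execution, interferon response, heat shock and unfolded protein response, glucose metabolism, cell cycle, blood, vessel, muscle, heart, neural, neural crest, notochord, hatching gland, lens, epidermis, yolk syncytial layer and liver, endoderm and gut, germ line, Hox, somite and presomitic mesoderm, respiratory chain and ribosomal protein genes. They held 991 entries, of which 14 matched no symbol and 759 were measured. Lists were tested with camera at a preset correlation of 0.01, against camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the 25 lists of a comparison. Counts of members past the threshold are given over all probes and, for some lists, also adjusted over the list alone.

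The procedure was tested on simulated arrays with a smooth dye curve and 200 changed probes, under 2 models of the probes' variances. With variances drawn from the fitted prior, which is what limma assumes, 12 of 67 changes of 1.25-fold, 63 of 67 of 1.5-fold and 66 of 66 of 2-fold were recovered at 12 hpf, with 13 false among 154 calls. For the difference between ages 1, 41 and 66 of the same numbers were recovered. For the wild type at 24 against 12 hpf these were 0, 8 and 57, from log2 levels drawn directly, without a dye curve or normalization. The other model recovered 54 of 67 changes of 1.25-fold at 12 hpf. The first model tried took the probes' own moderated variances, and under it 59 of 246 calls at 12 hpf, 37 of 225 at 24 hpf and 22 of 158 of the difference were false. The prior-based model was added after that result was seen, and under it 7 of 145 calls at 24 hpf and 10 of 118 of the difference were false. The false share was above the nominal 5% at 12 hpf and for the difference under both models, and at 24 hpf under the first. The measured ratios gave 6103 calls at 12 hpf, far more than the simulated arrays. With more calls the adjustment admits larger unadjusted p, so the simulated recovery and false shares need not hold for the measured ratios. Of 20 simulated lists shifted by 0.2, camera with a preset correlation called 20 with 1 false call among 100 unshifted lists, fry called 19 and 0, and camera with an estimated correlation 0 and 0. Ratios for these lists were also drawn directly, without the steps of normalization. Members of these lists were drawn independently, so false calls among correlated members could not be judged. In the measured ratios the estimated correlation ranged from −0.0623 for the Bcl-2 family to 0.389 for ribosomal proteins. It was 0.166 for p53 targets and 0.160 for the respiratory chain.

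Alternatives were an offset of 16, no background subtraction, the scanner software's processed signals, the deposited ratios, median centring in place of loess, Aquantile between arrays, median centring between arrays for the wild type, no filter or a stricter filter on dim probes, the replicate number as a block, eBayes with a trend or robust, an adjusted p of 0.1, each age fitted alone, the scanner software's p of 0.01 on both arrays, the mean of a gene's probes, and leaving out each array in turn. The replicate numbers share a number and nothing else in the labels, and the deviations of replicate 1 from its age mean correlated at −0.0408 between ages across probes, so no pairing was assumed. Groups of 2 allow neither a test for outlying arrays nor other splits of the samples.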

Results

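Whole-embryo RNA of zebrafish injected at the 1-cell stage with a morpholino against Bad was compared with wild-type RNA of the same age, at 12 and 24 hours post fertilization (hpf). Bad is a pro-apoptotic BH3-only member of the Bcl-2 family, and the series title names the function of the zebrafish Bad gene as its subject. Each age had 2 biological replicates of 200 embryos per group, each hybridized to its own 2-colour array with the morphant in Cy5 and the wild type in Cy3, so 4 arrays carried 8 labelled samples. The labels name no dye swap and no control morpholino, so treatment, injection and dye shared each ratio. The median spot signal was 52, 59, 76 and 73 in Cy3 over local backgrounds of 29, 31, 32 and 30 on 12 hpf replicates 1 and 2 and 24 hpf replicates 1 and 2. In Cy5 it was 92, 88.5, 131 and 136, over 49 on each of the last 3 arrays. Between 55.9% and 61.5% of the noncontrol probes were well above background in Cy3, and between 57.9% and 64.9% in Cy5. The 28321 probes kept for testing included 14500 with a gene symbol, for 10207 genes. Log2 ratios below are morphant over wild type, with SD over n = 2 arrays unless an SE is named, and the number of arrays limits their precision.

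The targeted gene was measured by 1 probe, for badb, and no probe carried the symbol bada. The labels name the target only as Bad, so taking badb as the targeted gene is an assumption. The badb log2 ratio was −0.30 and −0.20 on the 12 hpf arrays and −0.42 and −0.20 on the 24 hpf arrays, lower in the morphant on all 4. The mean was −0.25 ± 0.07 at 12 hpf (limma adjusted p = 0.0357) and −0.31 ± 0.15 at 24 hpf (adjusted p = 0.0160). The 12 hpf call was lost without 12 hpf replicate 1 (−0.20, adjusted p = 0.263) and without 12 hpf replicate 2 (−0.30, adjusted p = 0.0796), and the 24 hpf call without 24 hpf replicate 1 (−0.20, adjusted p = 0.236). With the scanner software's processed signals neither age passed (adjusted p = 0.159 and 0.129), and with median centring in place of loess the 12 hpf value was 0.14 (adjusted p = 0.782). The labels do not say whether the morpholino blocks translation or splicing.

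At 12 hpf, during segmentation, the morphants had less mRNA of the mesendodermal homeobox gene mixl1, which fell by 2.16 ± 0.20 (4.46-fold), and of the prolyl hydroxylase gene egln3, which fell by 1.98 ± 0.13 (3.95-fold). The survivin paralogue birc5b fell by 1.49 ± 0.16, the Cdk1-inhibiting kinase gene wee2 by 1.46 ± 0.37 and the p53 target phlda3 by 1.21 ± 0.02. Among the genes that rose, the transcriptional coactivator gene sub1b rose by 1.84 ± 0.05 (3.58-fold) and the maternal linker histone gene h1m by 1.56 ± 0.54. Further rises were lsm14b at 1.23 ± 0.42, the histone mRNA-binding slbp2 at 1.19 ± 0.15 and the RNA-binding fus at 1.14 ± 0.11. The remaining named rises were c6.2 (1.48 ± 0.03), the Ran GTPase-activating gene rangap1b (1.40 ± 0.17), cnpy2 (1.38 ± 0.07), tnfaip1 (1.34 ± 0.03) and the urate-pathway gene uraha (1.103 ± 0.07). The remaining named falls were tmem144b (−1.83 ± 0.07), tesca (−1.79 ± 0.12), the RNA-binding rbpms2b (−1.48 ± 0.35), rundc3ab (−1.46 ± 0.08) and the sialyltransferase gene st3gal8 (−1.18 ± 0.04). Each of these 20 genes moved the same way on both arrays, as the rule for naming required, with limma adjusted p between 1.6e-06 and 2.0e-04. The call of lsm14b was lost with the scanner software's processed signals or the deposited ratios, and those of rbpms2b, wee2, phlda3 and st3gal8 with median centring in place of loess.

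**Figure D1:**
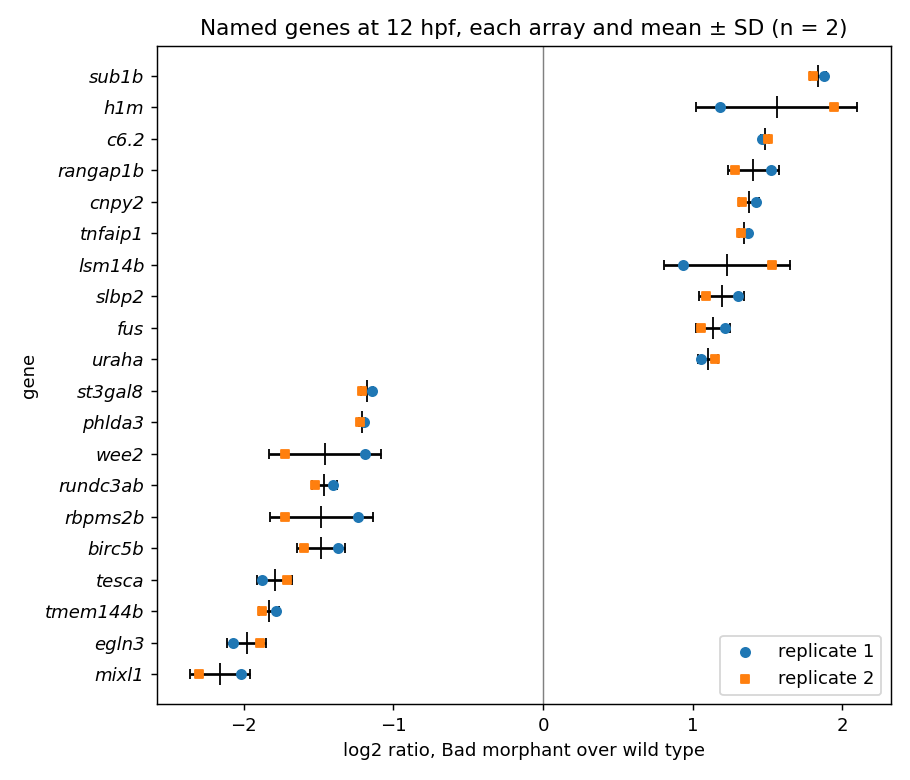
Log2 ratio of morphant over wild type at 12 hpf (x axis) for the 20 named genes (y axis), with circles and squares for the 2 arrays and bars for mean ± SD (n = 2). The rises lie between 1.103 for uraha and 1.84 for sub1b, and the falls between −1.18 for st3gal8 and −2.16 for mixl1.

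Targets of p53 were lower as a group at 12 hpf. Of 21 measured members 11 fell, 3 rose and 7 did not pass, with the same 11 and 3 adjusted over the list alone. Besides phlda3 they included the Bcl-2 family gene bbc3 (Puma, −0.78 ± 0.22), foxo3b (−0.78 ± 0.15) and the p53 ubiquitin ligase gene mdm2 (−0.74 ± 0.07). The camera test against all other genes gave adjusted p = 0.00259, and adjusted p = 0.699 with an estimated correlation. By fry the list did not pass (adjusted p = 0.108). With median centring in place of loess its plain mean was 0.11, though it stayed below all genes (−0.18). Ribosomal protein genes were higher, with 30 of 72 risen, 1 fallen and 41 not past the test (45 and 2 adjusted over the list alone; adjusted p = 1.5e-11, and 0.699 with an estimated correlation). Examples were rps18 (0.59 ± 0.04), rpsa (0.51 ± 0.03) and rpl22 (0.49 ± 0.10). Of 31 markers of the yolk syncytial layer and liver 12 rose, 4 fell and 15 did not pass (12 and 4 adjusted over the list alone; adjusted p = 0.0187, and 0.699 with an estimated correlation). Among them were the fatty-acid-binding genes fabp1b.1 (0.83 ± 0.20) and fabp2 (0.66 ± 0.11) and the retinol carrier gene rbp4 (0.59 ± 0.16). Of 30 cell cycle genes 8 rose, 0 fell and 22 did not pass (13 and 2 adjusted over the list alone; adjusted p = 0.0251, and 0.699 with an estimated correlation). They were led by the A-type cyclin gene ccna1 (1.00 ± 0.48) and the replication helicase gene mcm7 (0.44 ± 0.02). The cell cycle call was lost without 12 hpf replicate 2 (adjusted p = 0.160) and, with that of the yolk syncytial layer and liver, with the scanner software's processed signals (adjusted p = 0.109 for both) or the deposited ratios (0.0884 for both). The cell cycle call was also lost with only probes well above background in both channels on all 4 arrays (0.0755) and with the mean of a gene's probes (0.0791). By fry the ribosomal, yolk syncytial layer and liver, and cell cycle lists did not pass either (adjusted p = 0.108, 0.116 and 0.108).

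Over all probes at 12 hpf, limma called 3454 higher and 2649 lower in morphants at an adjusted p of 0.05, out of 28321, and 9995 had an unadjusted p under 0.05. By gene, taking the brightest probe, 1265 were higher and 1114 lower of 10207. Most changes were small, with a median absolute log2 ratio of 0.32 among the called probes. Of these 43 were higher and 30 lower by at least 2-fold. Without any test, 22 probes were at least 2-fold higher and 25 at least 2-fold lower on both arrays, and 0 went in opposite directions. The count fell to 2351 without 12 hpf replicate 1 and 4046 without 12 hpf replicate 2. It was 2192 with the scanner software's processed signals, 2275 with the deposited ratios, 983 by the scanner software's own p on both arrays and 337 with median centring in place of loess. Of the 337, 324 were higher and 13 lower, and of the 4046 without 12 hpf replicate 2, 2599 were higher and 1447 lower.

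At 24 hpf the morphants had less mRNA of the kinase gene pim2, which fell by 2.16 ± 0.54 (4.47-fold). The keratin genes krt99 and krt97 were at −1.68 ± 0.23 and −1.44 ± 0.08, and egln3 fell again by 2.13 ± 0.38 (4.38-fold). The linker histone gene h1-10 fell by 1.79 ± 0.23, the vitamin D-degrading cyp24a1 by 1.61 ± 0.15, the mTORC1 inhibitor gene ddit4 by 1.58 ± 0.35 and the planar cell polarity gene prickle1a by 1.53 ± 0.29. The eIF2α phosphatase subunit gene ppp1r15a (−1.27 ± 0.18) and the ventral homeobox gene ved (−1.248 ± 0.10) completed the named falls. The largest rise was that of s100a10a, which encodes an annexin partner, at 2.402 ± 0.67 (5.28-fold). The GTPase gene rab12 rose by 1.16 ± 0.43, the RNA polymerase III factor gene brf1a by 1.03 ± 0.14, the U6 RNA-processing gene usb1 by 0.89 ± 0.12 and the microRNA-processing gene dgcr8 by 0.80 ± 0.02. Further rises were cnpy2 (0.91 ± 0.08), plgrkt (0.82 ± 0.23), cldnd (0.80 ± 0.46) and the lens gene lim2.4 (0.79 ± 0.01). The mean of cldnd1a was 1.28 ± 1.51, from 2.34 and 0.22 on the 2 arrays (adjusted p = 0.0306), and its call was also lost without 24 hpf replicate 1, with the smaller background offset and with robust eBayes. Limma adjusted p of the other 19 lay between 8.9e-06 and 0.00268, and all 20 moved the same way on both arrays, as the rule for naming required. All 20 lost their call with the scanner software's processed signals and with median centring in place of loess, and 11 of them with the deposited ratios.

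**Figure D2:**
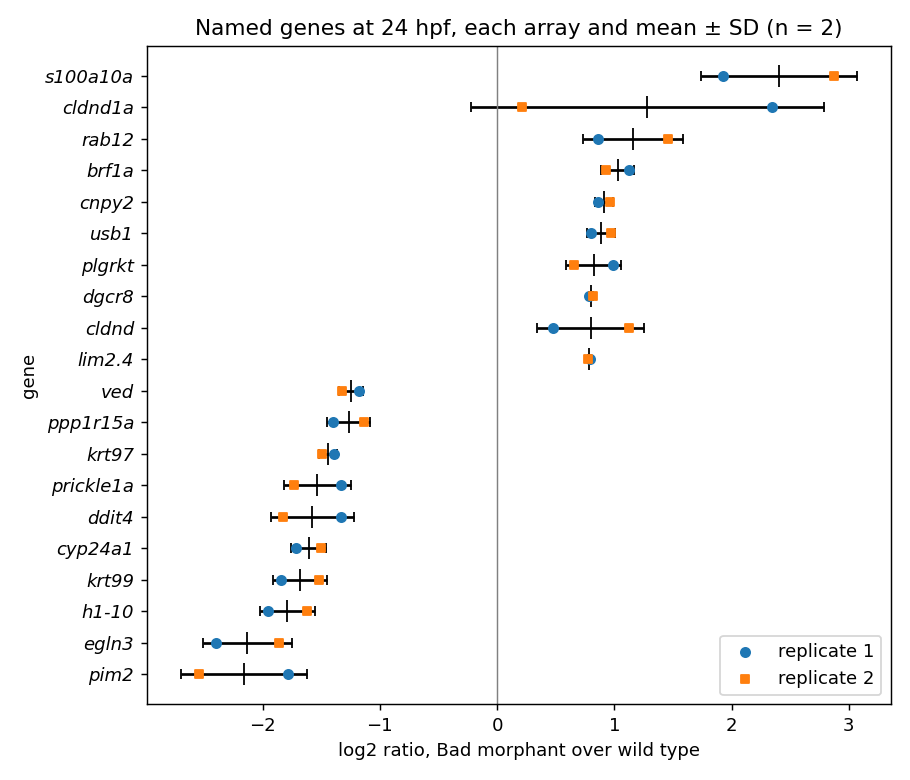
Log2 ratio of morphant over wild type at 24 hpf (x axis) for the 20 named genes (y axis), with circles and squares for the 2 arrays and bars for mean ± SD (n = 2). The arrays lie far apart for cldnd1a (2.34 and 0.22), and egln3 and pim2 lie lowest at −2.13 and −2.16.

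Genes of the unsegmented posterior mesoderm and of somite formation were lower as a group at 24 hpf. Of 33 measured members 19 fell, 1 rose and 13 did not pass (21 and 1 adjusted over the list alone), including the T-box genes tbx16 (−1.05 ± 0.30) and tbx16l (−0.95 ± 0.11), the retinoic acid-degrading cyp26a1 (−1.01 ± 0.08) and fgf17 (−0.96 ± 0.03). Camera gave adjusted p = 7.7e-08, and 0.275 with an estimated correlation. Notochord genes were lower, with 13 of 21 fallen, 0 risen and 8 not past the test (14 and 0 adjusted over the list alone; adjusted p = 1.8e-04, and 0.334 with an estimated correlation). Examples were the homeobox gene noto (−0.61 ± 0.11) and foxa2 (−0.52 ± 0.01). Of 14 hatching gland genes 9 fell, 1 rose and 4 did not pass (10 and 1 adjusted over the list alone; adjusted p = 5.1e-04, and 0.275 with an estimated correlation). They included the hatching enzyme genes he1.2 (−0.63 ± 0.00) and he1.1 (−0.43 ± 0.02). Of 34 epidermal and keratin genes 12 fell, 2 rose and 20 did not pass (18 and 3 adjusted over the list alone; adjusted p = 5.5e-04, and 0.275 with an estimated correlation). Among these, krt94 rose by 0.52 ± 0.05 while krt99, krt97 and krt18a.1 (−0.60 ± 0.13) fell. Endoderm and gut genes had 9 fallen, 1 risen and 11 not past the test of 21 (9 and 2 adjusted over the list alone; adjusted p = 0.0218, and 0.334 with an estimated correlation), including gata5 at −0.61 ± 0.15 and the pancreatic ptf1a at 0.48 ± 0.20. Of 33 genes of glucose metabolism 12 fell, 3 rose and 18 did not pass (14 and 4 adjusted over the list alone; adjusted p = 0.0344, and 0.334 with an estimated correlation). Of these the glycolytic gpia was at −0.90 ± 0.12 and ldha at −0.71 ± 0.26.

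Lens, muscle, respiratory chain and ribosomal protein genes were higher as groups at 24 hpf. Of 27 lens crystallin and lens genes 13 rose, 0 fell and 14 did not pass (13 and 1 adjusted over the list alone; adjusted p = 1.5e-04, and 0.275 with an estimated correlation), with cryba1b at 0.79 ± 0.11 and crygn2 at 0.50 ± 0.05. Skeletal muscle genes had 15 risen, 5 fallen and 23 not past the test of 43 (18 and 6 adjusted over the list alone; adjusted p = 5.5e-04, and 0.275 with an estimated correlation). The creatine kinase gene ckmb rose by 0.50 ± 0.04 and mylz3 by 0.48 ± 0.07, while the myogenic factor gene myf5 (−0.96 ± 0.08) and the slow myosin gene smyhc1 (−0.49 ± 0.23) fell. Of 43 respiratory chain genes 13 rose, 2 fell and 28 did not pass (20 and 2 adjusted over the list alone; adjusted p = 2.9e-05, and 0.513 with an estimated correlation). Of these cycsb, a cytochrome c gene, rose by 0.62 ± 0.16 and the succinate dehydrogenase gene sdhb by 0.50 ± 0.17. Of 72 ribosomal protein genes 31 rose, 2 fell and 39 did not pass (34 and 2 adjusted over the list alone; adjusted p = 2.9e-08, and 0.612 with an estimated correlation). Of these rpl22 rose by 0.57 ± 0.11 and rps12 by 0.56 ± 0.10. The muscle call was lost when only probes well above background in both channels on all 4 arrays were kept (adjusted p = 0.0570), and the ribosomal call with the scanner software's processed signals (adjusted p = 0.0657) or the deposited ratios (0.0697). By fry the respiratory chain and ribosomal lists did not pass (adjusted p = 0.0667 for both). The glucose call was lost with no background subtraction (0.0675), no filter on dim probes (0.0573), processed signals (0.159) and the deposited ratios (0.171). With median centring in place of loess the calls of the glucose, notochord, hatching gland, lens, epidermis and endoderm lists were lost. That setting put the median of all genes at 0.283 at 12 hpf and 0.245 at 24 hpf, and without removing this shift the plain means of the glucose (0.24), notochord (0.12), hatching gland (0.11), epidermis (0.24) and endoderm (0.11) lists lay above 0.

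Over all probes at 24 hpf, limma called 2885 higher and 3088 lower in morphants of 28321, with 9984 at an unadjusted p under 0.05, and by gene 1238 higher and 1436 lower of 10207. The median absolute log2 ratio of the called probes was 0.31, with 12 higher and 55 lower by at least 2-fold. On both arrays 1 probe was at least 2-fold higher, 34 were at least 2-fold lower and 0 went in opposite directions. The count was 2457 without 24 hpf replicate 1, 2654 without 24 hpf replicate 2 and 3874 with the smaller background offset. It was 796 by the scanner software's own p, 100 with the deposited ratios, 15 with the scanner software's processed signals and 1 with median centring. With no background subtraction it was 6123.

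Cell death genes moved both ways, as did genes in general. Of all 10207 genes 1265 were called higher and 1114 lower at 12 hpf, and 1238 and 1436 at 24 hpf. Of 17 measured Bcl-2 family genes 3 rose and 2 fell at 12 hpf (4 and 4 adjusted over the list alone; adjusted p = 0.937), and 6 rose and 4 fell at 24 hpf (7 and 6; adjusted p = 0.648). The anti-apoptotic mcl1b fell by 1.07 ± 0.11 and bnip3lb by 0.71 ± 0.14 at 24 hpf, where bcl2l13 rose by 0.61 ± 0.01. Of 21 caspase and execution genes 3 rose and 2 fell at 12 hpf (3 and 2 adjusted over the list alone; adjusted p = 0.937) and 2 rose and 5 fell at 24 hpf (3 and 5; adjusted p = 0.546), with the initiator caspase gene casp8 at −0.67 ± 0.28 at 12 hpf. At 24 hpf the p53 targets had 5 risen and 1 fallen of 21 (5 and 1 adjusted over the list alone; adjusted p = 0.277). This list passed without 24 hpf replicate 2 (adjusted p = 0.0226) and with median centring in place of loess (0.25 relative to all genes, 0.00355). Of 30 cell cycle genes 4 rose and 5 fell at 24 hpf (4 and 5 adjusted over the list alone; adjusted p = 0.602). With median centring this list passed in the other direction (0.20, adjusted p = 0.00731). Bcl-2 family means at 24 hpf and caspase means at 12 hpf lay below 0 (−0.01 and −0.04) while the test pointed up.

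Blood and vessel markers did not pass as groups at either age, but the erythroid list passed at 24 hpf with median centring in place of loess (0.21 relative to all genes, adjusted p = 0.00731). Erythroid genes had 3 risen and 2 fallen of 27 at 12 hpf (adjusted p = 0.937) and 9 risen and 5 fallen at 24 hpf (11 and 6 adjusted over the list alone; adjusted p = 0.131), where the embryonic globin gene hbbe3 rose by 0.58 ± 0.04 and gfi1aa fell by 1.15 ± 0.10. Myeloid genes had 1 risen and 1 fallen of 19 at 12 hpf (adjusted p = 0.766) and 3 and 4 at 24 hpf (0.663), and endothelial genes 4 and 2 of 20 (0.937) and then 4 and 5 (0.525). Of 16 heart genes 2 rose and 1 fell at 12 hpf (adjusted p = 0.937) and 4 and 3 at 24 hpf (0.602). Of 70 neural genes 11 rose and 5 fell at 12 hpf (adjusted p = 0.288) and 8 rose and 20 fell at 24 hpf (11 and 25 adjusted over the list alone; 0.0590), when rx3, a homeobox gene of the eye field, fell by 0.90 ± 0.02. The neural list passed at 24 hpf without 24 hpf replicate 2 (adjusted p = 0.0413). Of 27 neural crest and pigment genes 4 rose and 1 fell at 12 hpf (adjusted p = 0.584) and 10 and 7 at 24 hpf (0.460). Of 13 germ line genes 6 rose and 2 fell at 12 hpf (adjusted p = 0.132) and 1 and 3 at 24 hpf (0.811), and of 46 Hox genes 9 rose and 1 fell (0.132) and then 6 and 10 (7 and 14 adjusted over the list alone; 0.304). The Hox list passed at 12 hpf without 12 hpf replicate 1 (adjusted p = 0.0388). With median centring the heart (−0.22, adjusted p = 0.0265) and germ line (0.23, 0.0295) lists passed at 12 hpf.

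Among stress genes, the heat shock and unfolded protein response list had 5 risen and 2 fallen of 28 at 12 hpf (adjusted p = 0.288) and 6 and 5 at 24 hpf (0.821). Adjusted over the list alone, its counts were 8 and 3 at 12 hpf and 6 and 10 at 24 hpf. The stress-induced transcription factor gene atf4b rose by 0.78 ± 0.02 at 24 hpf. Of 15 interferon response genes 2 rose and 3 fell at 12 hpf (2 and 6 adjusted over the list alone; adjusted p = 0.288) and 2 and 2 at 24 hpf (0.479). With median centring the heat shock list passed at both ages (0.23 and 0.20; 0.00327 and 0.00753), and the interferon list at 12 hpf (−0.28; 0.00470). At 12 hpf no group call was made for glucose metabolism (2 risen, 7 fallen of 33; adjusted p = 0.550), skeletal muscle (4 and 0 of 43; 0.305), notochord (0 and 0 of 21; 0.550), hatching gland (2 and 1 of 14; 0.937), lens (0 and 0 of 27; 0.777) or epidermis (10 and 3 of 34; 0.132). The same held for endoderm and gut (1 and 2 of 21; 0.631), somite and presomitic mesoderm (8 and 3 of 33; 0.584) and the respiratory chain (4 and 4 of 43; 0.937). With median centring 5 of these lists passed, relative to all genes. They were lens (−0.34, adjusted p = 9.3e-06), respiratory chain (0.24, 2.9e-04), epidermis (0.21, 0.00387), somite and presomitic mesoderm (0.17, 0.0219) and skeletal muscle, in the other direction (−0.15, 0.0219). The lens gene lim2.4 and the muscle genes atp2a1, mylpfa, myl1 and ckmb were not well above background in either channel at 12 hpf. Low signal therefore limits the lens and muscle results at that age. At 24 hpf the yolk syncytial layer and liver list had 3 risen and 5 fallen of 31 (adjusted p = 0.460). Across the 25 lists, camera with a preset correlation called 4 at 12 hpf and 10 at 24 hpf. With an estimated correlation it called 0 at both ages, and that test also called 0 of 20 shifted lists in simulated data. The simulated members were independent, so that simulation could not show how the preset correlation performs for correlated members. The fry test called 0 at 12 hpf and 9 at 24 hpf, where it also passed the neural list (0.0406).

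**Figure D3:**
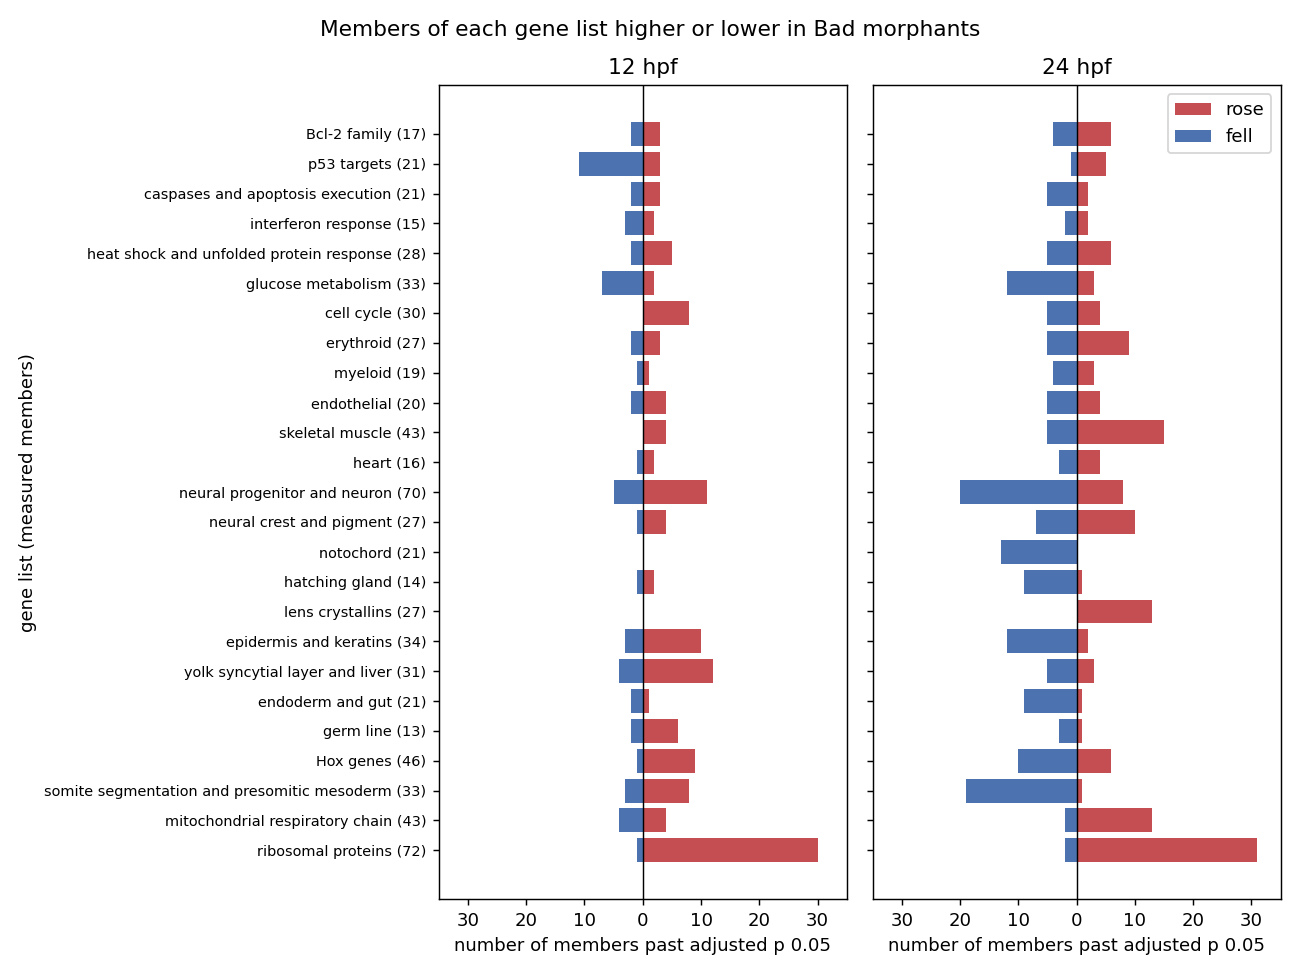
Number of members of each of the 25 gene lists (y axis, measured members in brackets) that rose (right of 0) or fell (left of 0) in morphants at adjusted p of 0.05, at 12 and 24 hpf. Ribosomal protein genes have 30 and 31 risen members, and the somite and presomitic mesoderm list goes from 8 risen and 3 fallen at 12 hpf to 1 risen and 19 fallen at 24 hpf, under loess normalization within arrays.

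The morphant effect was next compared between the ages, as the 24 hpf log2 ratio minus the 12 hpf log2 ratio, in which a dye effect common to all arrays cancels. The p53 targets phlda3 and bbc3 went from lower at 12 hpf (−1.21 and −0.78) to higher at 24 hpf (0.35 and 0.33), differences of 1.56 ± 0.13 and 1.12 ± 0.12 (SE). The largest upward difference was that of s100a10a, 2.29 ± 0.23 (SE), which was 0.11 at 12 hpf and whose call was lost with robust eBayes. Genes lower at 12 hpf and near 0 at 24 hpf were tmem144b (difference 1.79), rundc3ab (1.58), rbpms2b (1.51), wee2 (1.503), birc5b (1.296) and the immediate-early gene fosab (1.15), and tesca differed by 1.101. In the wild type tmem144b and wee2 had fallen to log2 levels of 6.77 and 6.85 at 24 hpf. Genes not well above background at 12 hpf had levels there such as 6.15 for lim2.4 and 6.41 for mylpfa. The 24 hpf ratios of tmem144b and wee2 may thus be pulled toward 0 by the low signal. The largest downward difference was −2.24 ± 0.20 (SE) for pim2, which was 0.08 at 12 hpf. The genes cyp24a1, ved, histh1l1, tbx16 and cyp26a1 were higher at 12 hpf and lower at 24 hpf, with differences of −2.04, −1.83, −1.38, −1.37 and −1.28. The other downward differences were h1-10 (−1.77), krt99 (−1.62), prickle1a (−1.56) and c6.2 (−1.29). All 20 lost their call with the scanner software's processed signals, the deposited ratios and median centring in place of loess. Limma adjusted p of these 20 lay between 4.8e-05 and 0.00219. The rule for naming required the same sign in all 4 differences between single arrays of the ages.

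**Figure D4:**
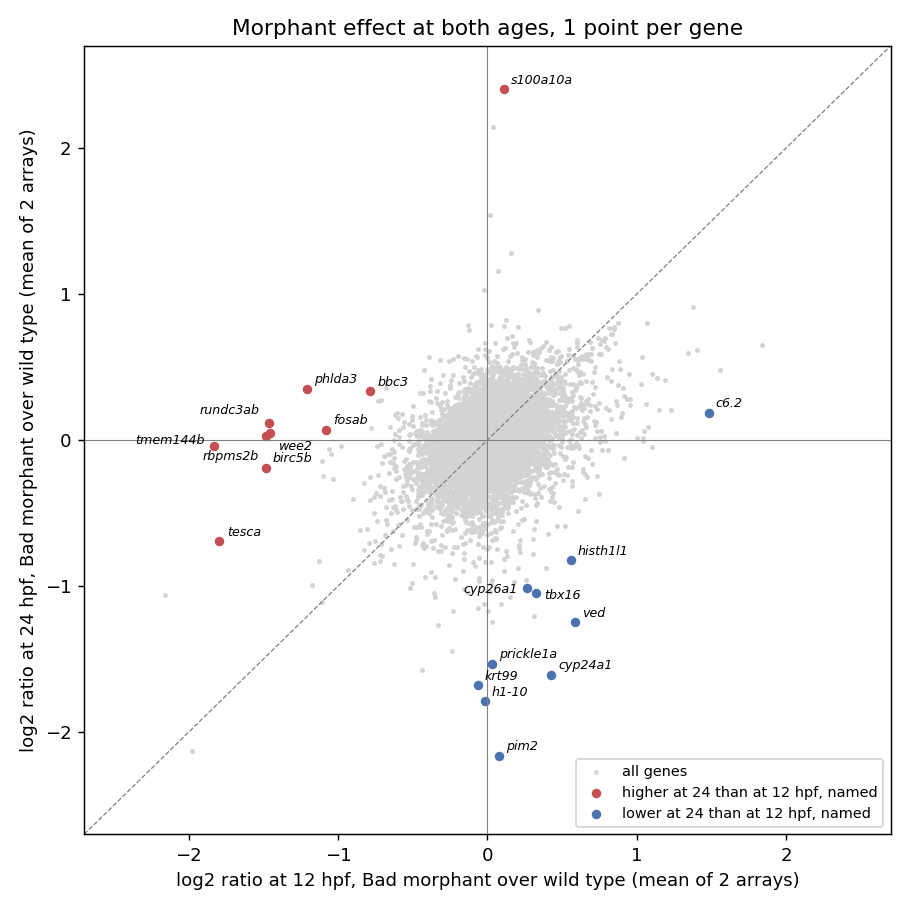
Mean log2 ratio of morphant over wild type at 12 hpf (x axis) against that at 24 hpf (y axis), 1 grey point per gene for 10207 genes, with the named upward differences in red and downward differences in blue. The dashed line marks equal ratios, and the correlation across genes is 0.383.

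Somite and presomitic mesoderm genes shifted down between the ages by a mean of −0.42, with 18 of 33 members down and 2 up (20 and 3 adjusted over the list alone; adjusted p = 1.8e-07, and 0.323 with an estimated correlation). None of the 14 lists called here passed with an estimated correlation (adjusted p between 0.323 and 0.352), and fry called 3, the lens, epidermis and somite lists. The p53 targets shifted up by 0.37 (10 up, 1 down of 21; 11 and 1; adjusted p = 2.4e-04, and 0.344 with an estimated correlation), and epidermal genes shifted down, at −0.33 (13 down, 0 up of 34; 21 and 2; 1.7e-06, and 0.323). Lens genes shifted up by 0.23 (7 up, 0 down of 27; 9 and 0; adjusted p = 7.0e-05, and 0.323 with an estimated correlation), although cryba1b and lim2.4 were not well above background in either channel at 12 hpf. Respiratory chain genes shifted up by 0.15 (1 up, 0 down of 43; 1 and 0; adjusted p = 6.8e-05, and 0.352 with an estimated correlation). Downward shifts were also called for hatching gland (−0.25; 3 down and 0 up of 14), germ line (−0.23; 3 and 0 of 13), yolk syncytial layer and liver (−0.22; 10 and 3 of 31), notochord (−0.20; 5 and 0 of 21) and the cell cycle (−0.16; 5 and 0 of 30). The other downward calls were neural genes (−0.15; 13 and 0 of 70), Hox genes (−0.14; 8 and 2 of 46) and endoderm and gut (−0.13; 2 and 2 of 21). Skeletal muscle was called upward (mean 0.06, median 0.13, adjusted p = 0.0437, and 0.344 with an estimated correlation) with 4 members up and 4 down. Relative to all genes its mean turned to −0.0189 with processed signals, −0.0278 with the deposited ratios and −0.00112 with only probes well above background in both channels on all 4 arrays. Its members with the largest differences were down, such as myf5 (−0.90) and mef2ca (−0.84). The other 11 lists did not pass, with adjusted p from 0.0566 for interferon response (2 up, 0 down of 15) to 0.845 for the Bcl-2 family (3 up, 2 down of 17), whose mean of −0.01 lay below 0 while the test pointed up. Median centring in place of loess ended the neural (adjusted p = 0.279), notochord (0.136), yolk syncytial layer and liver (0.159), endoderm (0.224) and Hox (0.506) calls. Processed signals ended the germ line and endoderm calls (0.0550 for both), and so did the deposited ratios (0.0606 and 0.0949). The muscle and endoderm calls were also lost with the smaller background offset (0.209 and 0.0657) and with no background subtraction (0.260 and 0.0561), and the germ line call with the stricter filter (0.0655). The interferon response list passed with the smaller offset (0.0475), with no background subtraction (0.0363) and with the replicate number as a block (0.0446). With median centring the erythroid (0.28, adjusted p = 2.8e-05) and heart (0.20, 0.0216) lists passed. The skeletal muscle and endoderm calls were lost without 12 hpf replicate 1 (adjusted p = 0.111 and 0.0607) and without 24 hpf replicate 1 (0.118 and 0.0720). Without 12 hpf replicate 2 the endoderm (0.0719), germ line (0.0564) and Hox (0.0604) calls were lost, without 24 hpf replicate 1 that of the germ line (0.206) and without 24 hpf replicate 2 that of the endoderm (0.0703). The interferon response list passed without 12 hpf replicate 1 (0.0293) and the ribosomal list without 24 hpf replicate 1 (0.00990).

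Limma called 881 probes with an upward and 1515 with a downward difference between the ages of 28321 (408 and 698 of 10207 genes), 30 and 68 of them by at least 2-fold. The count was 1268 without 12 hpf replicate 1, 1195 without 24 hpf replicate 1, 1387 without 24 hpf replicate 2 and 826 with the smaller background offset. Limma called 0 with the scanner software's processed signals, with the deposited ratios or with median centring, against 7162 probes at an unadjusted p under 0.05 in the fit reported here. With no background subtraction it called 1822.

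Across genes, which are not independent replicates, the mean log2 ratios at the 2 ages had a Pearson r of 0.383 and a Spearman rho of 0.372, and 62.9% of 10207 genes had the same sign. The 2 arrays of an age correlated at 0.734 at 12 hpf and 0.702 at 24 hpf, and arrays of different ages at 0.308 to 0.359. Of the called probes 1050 were higher and 865 lower at both ages, where independent lists of these sizes would share 352 and 289. In opposite directions, 159 were higher at 12 hpf and lower at 24 hpf and 62 the reverse, where independent lists would share 377 and 270. Genes in the shared group included egln3, st3gal8 and mixl1 (lower) and sub1b, cnpy2, rangap1b, tnfaip1 and dgcr8 (higher).

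The wild-type channel alone gave the normal change from 12 to 24 hpf as a scale. The embryonic globin gene hbbe3 was 851-fold higher at 24 hpf, the myosin light chain gene myl13 368-fold and the aldolase gene aldoab 308-fold. The 12 hpf log2 level of hbbe3 was only 6.69, though well above background, so low signal may have made its fold too small. The calcium pump gene atp2a1 was at least 497-fold higher, mylpfa at least 470-fold, myl1 at least 436-fold, ckmb at least 309-fold and pvalb2 at least 189-fold, since these were not well above background at 12 hpf. In log2 units tnnc2.2 rose by 8.10 ± 0.11 (SE) and tuba8l3 by 7.62 ± 0.14 (SE). Among the falls were six7 at −6.32 ± 0.09 (SE), the organizer genes gsc at −5.75 ± 0.08 and chrd at −4.72 ± 0.12, the endoderm factor gene sox32 at −5.67 ± 0.08 and cdx1a at −5.36 ± 0.09. The other named falls were nnr (−5.39), wee2 (−5.18), alox5b.3 (−4.82), frzb (−4.59) and tmem144b (−4.36). Limma adjusted p of these 20 lay between 8.9e-08 and 5.4e-07, in a comparison of 2 arrays with 2.

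Of the 25 lists 14 rose and 3 fell in the wild type. Skeletal muscle genes rose by a mean of 4.48 (41 of 43 up, 2 down; adjusted p = 1.3e-16), erythroid genes by 2.16 (22 up, 3 down of 27; 2.4e-06), endothelial genes by 1.74 (15 up, 2 down of 20; 1.5e-04) and glucose metabolism genes by 1.66 (25 up, 4 down of 33; 1.8e-05). Germ line genes fell by 1.51 (0 up, 11 down of 13; 3.3e-04), somite and presomitic mesoderm genes by 1.103 (3 up, 25 down of 33; 1.3e-04) and cell cycle genes by 0.54 (1 up, 20 down of 30; 0.00218). All 17 were lost with an estimated correlation (adjusted p between 0.316 and 0.556), and fry called 24. Limma called 8244 probes higher and 11287 lower of 28321, with 3140 and 2576 by at least 2-fold, where 12 hpf morphants differed from wild type by 2-fold at 43 and 30.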

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

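The tests for morphants further along in development than the wild type were chosen after the results were seen. Each result given here was picked out because the morphant effect differed between 12 and 24 hpf by a test of the difference itself, limma for genes and camera for lists, and the difference passed for 2396 probes. Under the scanner software's processed signals, the deposited ratios and median centring 0 probes passed, and with no background subtraction 1822 did.

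Among gene lists, mean log2 differences (24 minus 12 hpf) were 0.37 for p53 targets, 0.23 for lens genes, 0.15 for the respiratory chain and 0.0602 for skeletal muscle, none of which passed with an estimated correlation (adjusted p between 0.323 and 0.352). The plain mean of skeletal muscle turned to −0.0197, −0.0300 and −0.0265 under processed signals, the deposited ratios and the stricter filter. Relative to all genes it was −0.0189, −0.0278 and −0.00112 there. Those below 0 were −0.42 for somite and presomitic mesoderm, −0.33 for epidermis, −0.25 for hatching gland, −0.23 for germ line, −0.22 for yolk syncytial layer and liver, −0.20 for notochord, −0.16 for the cell cycle, −0.15 for neural genes, −0.14 for Hox genes and −0.13 for endoderm and gut, and none of these passed with an estimated correlation (same range of adjusted p). Single genes with upward differences were s100a10a (2.29), tmem144b (1.79), rundc3ab (1.58), phlda3 (1.56), rbpms2b (1.51), wee2 (1.503), birc5b (1.296), fosab (1.15), bbc3 (1.12) and tesca (1.101). Low signal at 24 hpf limits the values of tmem144b and wee2. Downward differences were those of pim2 (−2.24), cyp24a1 (−2.04), ved (−1.83), h1-10 (−1.77), krt99 (−1.62), prickle1a (−1.56), histh1l1 (−1.38), tbx16 (−1.37), c6.2 (−1.29) and cyp26a1 (−1.28).

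The somite list was lower and the lens, muscle, respiratory chain and ribosomal lists higher at 24 hpf, the direction of the wild-type change for these lists. At 12 hpf the ribosomal list (0.22, wild type 0.23, camera adjusted p = 0.00405) also went that way. So did the yolk syncytial layer and liver list at 12 hpf (0.16, wild type 1.35, 0.0132). Such shifts could come from morphants further along in development than their wild type. They were unlike in size relative to the wild-type change, with muscle at 24 hpf at 0.12 against 4.48. The ribosomal mean was similar at both ages (0.22 and 0.18), and the difference did not pass (camera adjusted p = 0.325). A dye bias common to all arrays could give that as well. At 24 hpf glucose metabolism (−0.16) and epidermis (−0.22) went against the wild-type change, since both rose in the wild type (1.66 and 1.16, camera adjusted p = 1.8e-05 and 0.0330). The epidermal genes krt99 and krt97, however, fell in the wild type too (−1.28 and −1.13). Against the wild-type change at 12 hpf went p53 targets (−0.30, wild type 0.60, adjusted p = 0.0151) and the cell cycle (0.13, wild type −0.54, 0.00218). With an estimated correlation all these wild-type list calls were lost (adjusted p between 0.316 and 0.556). A general delay would give a negative correlation across genes between the morphant ratio and the wild-type change taken from the other replicate, and at 24 hpf these correlations were 0.0489 and 0.0788, which argues against it. Both lie above 0, as a modest general advance would give, so an advance stays open, as it does at 12 hpf (0.0745 and 0.112). A shift in timing restricted to some tissues also stays open.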

How the results depend on the processing

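With no background subtraction 6552, 6123 and 1822 probes changed at 12 hpf, at 24 hpf and between the ages. With the scanner software's processed signals they were 2192 at 12 hpf, 15 at 24 hpf and 0 for the difference between ages, and with the deposited ratios 2275, 100 and 0. Both gave 379 probes 2-fold on both arrays at 12 hpf and 238 at 24 hpf, 2 lists past the threshold at 12 hpf, badb at −0.22 and −0.30 without passing, and correlations between ages of 0.340 and 0.343. Median centring in place of loess gave 337, 1 and 0 changed probes, 161 and 60 probes 2-fold, a correlation of 0.589, 13 lists at 12 hpf, and badb at 0.14, the other direction, and −0.0210. An offset of 16 gave 3874 probes at 24 hpf, 826 for the difference and badb at −0.26 at 12 hpf (adjusted p = 0.0696). An adjusted p of 0.1 gave 4181 for the difference, and the scanner software's p gave 983 and 796. Camera with an estimated correlation passed 0, 0 and 0 lists, and fry 0 at 12 hpf and 3 for the difference. Relative to all genes, the skeletal muscle difference between ages turned to −0.0189 with processed signals, −0.0278 with the deposited ratios and −0.00112 with only probes well above background in both channels on all arrays. Apart from the threshold of 0.1, which admits more probes by construction, the cause was not tested.

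Leaving out 1 array, where the lone array of an age is assumed to vary like the other age, gave 2351 to 6295 changed probes at 12 hpf, 2457 to 6741 at 24 hpf and 1195 to 2189 for the difference. The correlation ranged from 0.340 to 0.379, and badb from −0.30 to −0.20 at 12 hpf and −0.42 to −0.20 at 24 hpf. The number of lists past the threshold stayed at 3 to 5, 10 to 12 and 11 to 13. With the replicate number as a block 5920, 5764 and 2439 probes passed.

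Of 899 results of named genes under alternatives 778 kept direction and call, 121 lost the call and 0 reversed. For called lists 357 of 448 stayed, 88 lost the call and 3 reversed, the muscle values above. List means of the reported fit are plain means. For this comparison between settings list values are taken relative to the mean of all genes, a choice made after plain means were seen to turn above 0 under median centring for p53 targets at 12 hpf (0.11) and at 24 hpf for glucose (0.24), notochord (0.12), hatching gland (0.11), epidermis (0.24) and endoderm (0.11). Aquantile left ratios unchanged and so tested nothing. Its 60 results of named genes and those of the 28 called lists are nevertheless among the results counted as kept. Leaving out an array of the other age also leaves a gene's mean ratio at an age unchanged, so only the call could be lost there. The kept counts therefore overstate how far the results were tested. The wild-type count ranged from 15932 to 21201. Median Cy3 signals of 52 to 76 over backgrounds of 29 to 32 limit what can be said of dim probes.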

Other observations

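The test of Hif targets and the tests of dye bias below were chosen after the results were seen. Some genes induced by the oxygen-sensing Hif transcription factors were lower in morphants. The prolyl hydroxylase gene egln3 was at −1.98 and −2.13 at 12 and 24 hpf, the collagen prolyl hydroxylase gene p4ha1b at −1.11 and −1.11, ddit4 at −0.44 and −1.58, and the glycolytic genes pfkfb3 at −1.03 and −0.27 and eno1a at −1.06 and −0.06. At 24 hpf pfkfb3 and eno1a did not pass (limma adjusted p = 0.0821 and 0.591). These 5 were noticed while the results were browsed, and a list of other Hif targets was then written without them. Of its 33 measured genes 10 fell, 1 rose and 22 did not pass at 12 hpf, and 13 fell, 4 rose and 16 did not pass at 24 hpf. They included p4ha2 (−0.52 and −1.01), plod1a (−0.65 and −0.74), pfkfb4b (−0.62 and −0.85) and wsb1 (−0.50 and −0.85), while igfbp1b was at 0.64 ± 0.66 (SD) at 12 hpf and hmox1a at 0.34 at 24 hpf. Also counted as fallen at both ages were hif1an (−0.38 and −0.32) and vhl (−0.33 and −0.35). Both restrain Hif, so their lower levels by themselves would not lower its activity. The list also held the Hif subunit genes epas1a and epas1b, which did not pass at either age.

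Lower Hif activity in the morphants may account for this group. The mean of the other listed genes, with hif1an and vhl included, was −0.17 relative to all genes at 12 hpf (camera p = 3.4e-04, 0.0620 with an estimated correlation) and −0.20 at 24 hpf (p = 0.00161, 0.0779 with an estimated correlation). It was not taken without hif1an and vhl. Dye bias of single probes could be tested only for eno1a, whose other probe averaged −0.207 over both ages, so it stays open. That probe gave −0.17 at 12 hpf and −0.25 at 24 hpf, against −1.06 and −0.06 for the probe named above, so the size of the 12 hpf fall of eno1a and its pattern over age did not hold on it. Dye bias of the transcripts and differences in rearing density or oxygen between the pools stay open, and neither was tested.

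Ratios shared by both ages could come from the morphant always being in Cy5. Among 2548 genes whose wild-type level did not pass the test for a change between ages the correlation between ages across genes was 0.494, against 0.347 for the other 7659, which dye bias would give and a lasting effect of the morpholino could give as well. Against bias of single probes, the 2 brightest probes of 3464 genes correlated across genes at 0.591 for the mean of both ages, so bias of single probes is not the whole cause. That was below 0.620 at 12 hpf, 0.641 at 24 hpf and 0.718 for the difference between ages, where a constant dye bias cancels, so a part from single probes stays open. Dye bias common to all probes of a transcript stays open, and only arrays with the dyes exchanged could separate it.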
